A study of Mus musculus with 20 samples.

How the data were processed

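RNA-seq and ribosome profiling (Ribo-seq) libraries were made from the livers of 10 mice, and each of the 20 libraries is 1 column of the deposited table. Per the labels, RNA was purified with Qiagen RNeasy, RNA libraries were made with the KAPA mRNA capture kit at day 9 and NeoPrep at day 13, and footprint libraries with Epicenter ART-seq on both days. The values are expected counts per gene symbol as deposited by the authors, who name cutadapt, Bowtie and Bowtie2 in their processing notes. Their versions, roles, the genome build and the counting rule are not given in the sources used here. Of the nonzero values, 44.3% are not whole numbers, and 100% lie within 0.01 of a multiple of 1 over 6, as when a read with up to 3 matching places is divided equally between them. The table holds 38784 symbols, of which 26502 are in the table of gene names and 29675 in the RefSeq gene table used to look up neighbours. No genome sequence was at hand, so GC content and mapping were not checked.

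Counts were rounded to whole numbers. Samples were grouped by siRNA (Eif3m or scrambled luciferase control), day and assay, from the labels. RNA libraries and footprint libraries were fitted separately in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM scaling and the robust quasi-likelihood F test over the 4 groups of an assay, so that both days share 1 estimate of spread. Translational efficiency was the footprint change minus the RNA change in 1 model over the 20 libraries. It did not pair the libraries of an animal, and TMM factors were computed within each assay. The 9 comparisons were Eif3m against control siRNA at day 9, at day 13, and the difference between these effects, for RNA, footprints and efficiency. Genes were called at a Benjamini-Hochberg adjusted p below 0.05, all tests two-sided. The SE of a log2 change is its size divided by the square root of the F statistic. CPM uses library totals times the TMM factor, and 0.5 CPM was added to both sides of ratios per animal. An exact test on ranks of 3 against 3 animals cannot go below a p of 0.1, so adjusted p values come from models that share spread across genes. Where leaving out a library leaves 1 animal in a group, that animal is assumed to vary like the other groups.

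The 36 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The lists cover the translation machinery, mitochondria, stress responses, inflammation, liver metabolism and secretion, cell types and other marker groups. They hold 1219 members, 1200 of them in the table. None of the 13 mitochondrially encoded mRNAs is in the table (0 of 13), so that list has no result, and lists with fewer than 3 tested members were not tested. Lists were tested against all other genes with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with camera at an estimated correlation and fry beside it. Members were also counted when adjusted over the list alone. Named genes are Eif3m and the other eIF3 subunits, the 8 largest rises and 8 largest falls of each comparison within a day among called genes whose groups did not overlap and whose mean was at least 5 CPM, and up to 4 called members of each list, or the 2 most abundant of a list with none. Gene models without a proper symbol were counted and not named. A gene named outside this rule is said to have been chosen after its values were seen.

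A ratio to a group with 1 to 3 counts is given with its exact 95% counting interval, and a group with 0 counts is set to a floor of 3 counts over the group. PCR duplicates cannot be recognised in such counts, so intervals and floors cover counting error only. Replicates of a group had Pearson r between 0.968 and 0.996 on log CPM over 16 pairs, with a chi-square per gene between 4.33 and 94.1, so they vary beyond counting error.

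Alternatives were DESeq2 size factors in edgeR, library totals alone, no filter beyond 1 count, a mean of at least 5 CPM, DESeq2 1.42.0, each day fitted alone, a block for the replicate number or, for efficiency, the animal, TMM over all libraries, limma on log ratios, and each library or animal left out in turn. A further alternative, genes whose control RNA differed under 4-fold between the days, was chosen after seeing the data. The same fits were tested on simulated data with known changes. In simulated RNA, 98% of 4-fold and 73% of 2-fold changes were called at day 9 and 88% and 36% at day 13. In footprints these were 94% and 66.7%, then 74% and 32.3%, and for efficiency 75% and 35%, then 44% and 6%. False calls were 9.95% of simulated calls in RNA at day 9 (19 genes) and 5.30% at day 13. In footprints they were 6.78% and 4.46%, and for efficiency 3.45% and 3.77%. RNA at both days and footprints at day 9 exceed the nominal 5%. In all 6 comparisons only the shifted list was called. Correlated genes and spreads that differ between the days were not simulated. Some genes are not reported here.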

Results

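RNA and ribosome footprints were sequenced from the livers of 10 FVB/N mice aged 6 to 8 weeks, each given lipid nanoparticles with siRNA at 0.5 mg/kg through the tail vein, 1 injection in 5 days. The siRNA was either a scrambled luciferase sequence, used as the control, or one against Eif3m, which encodes the m subunit of the translation initiation factor eIF3. Livers were taken at day 9 from 3 mice per group and at day 13 from 2 mice per group, and each animal gave 1 RNA library and 1 footprint library, 20 libraries in 8 groups. A footprint is the stretch of mRNA that a ribosome covers, so footprint counts follow both the amount of a message and how densely ribosomes occupy it. The day 9 RNA libraries were made with the KAPA mRNA capture kit and those of day 13 with NeoPrep, and all footprint libraries with ART-seq, so the RNA kit and the day cannot be told apart. Total counts per library ran from 27.4 to 39.02 M for day 9 RNA, from 4.96 to 26.4 M for day 13 RNA, from 4.50 to 7.69 M for day 9 footprints and from 1.64 to 6.52 M for day 13 footprints. The lowest RNA total, 4.96 M, belonged to day 13 Eif3m replicate 2. Albumin, the main plasma protein made by hepatocytes, took between 9.65% and 22.0% of the counts of a library.

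Eif3m itself was lower in every Eif3m siRNA library than in every control library, in RNA and in footprints, at both days. At day 9 (n = 3 per group) its RNA went from 74.6 ± 1.09 CPM (counts per 1 M counts after scaling, mean ± SD) to 7.73 ± 0.506, a log2 change of -3.27 (SE 0.16) with adjusted p = 5.5e-07, and its footprints from 75.9 ± 2.55 to 6.18 ± 0.542, a log2 change of -3.61 (SE 0.17) with adjusted p = 4.7e-11. At day 13 (n = 2 per group) its RNA went from 291 ± 70.0 to 17.7 ± 3.58 CPM, a log2 change of -4.01 (SE 0.21) with adjusted p = 9.6e-07, and its footprints from 77.6 ± 1.57 to 4.09 ± 2.30, a log2 change of -4.58 (SE 0.26) with adjusted p = 1.7e-09. The control level of Eif3m RNA was higher at day 13 than at day 9 while the control level of its footprints differed by less than the spread between replicates.

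**Figure D1:**
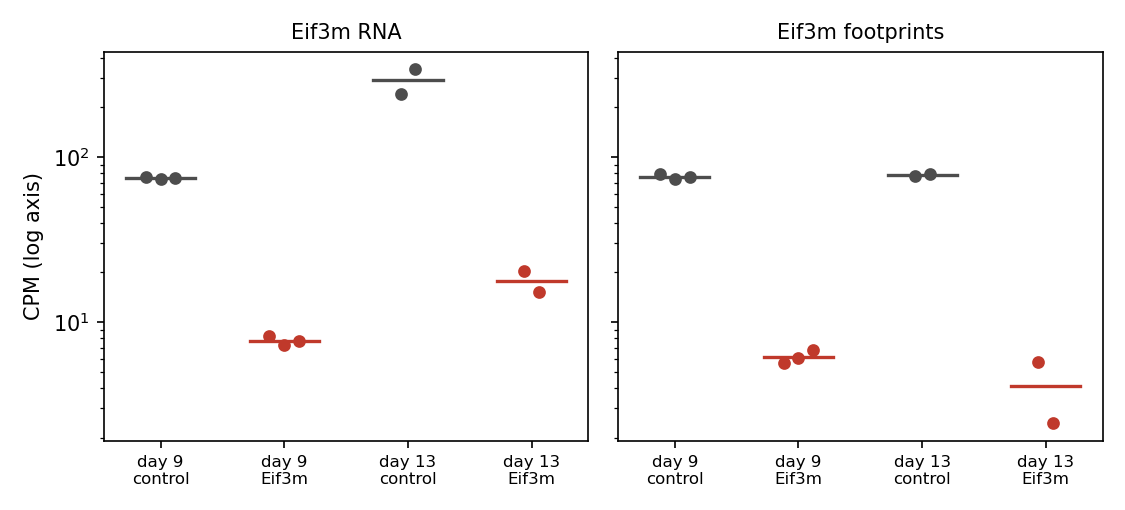
Eif3m in RNA and in footprints. Each point is 1 library, with CPM on a log axis against day and siRNA, and the line is the group mean; RNA means are 74.6 and 291 CPM in the controls and 7.73 and 17.7 CPM with Eif3m siRNA at day 9 and day 13.

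The first comparison asks how liver RNA differs with Eif3m siRNA at day 9 (n = 3 per group). Large rises included Arhgef2, a guanine nucleotide exchange factor for RhoA, at 3.14 (SE 0.29) on the log2 scale, Ddit3, which encodes the stress factor CHOP, at 2.62 (SE 0.20), Ifrd1 at 2.59 (SE 0.14), and the insulin-like growth factor binding protein gene Igfbp1 at 2.70 (SE 0.40). Large falls included the steroid hydroxylase Cyp17a1 at -4.49 (SE 0.69), Ugt1a5 at -2.75 (SE 0.23), Gstt3 at -2.65 (SE 0.16) and Acacb, an acetyl-CoA carboxylase, at -2.44 (SE 0.25). In all, 407 genes rose and 525 fell of 16444 tested (edgeR, adjusted p below 0.05), and 3382 had an unadjusted p below 0.05 where 822 would by chance. The called genes rested on the full set of libraries: 460, 485 and 305 were called without day 9 control replicate 1, 2 and 3, 356, 292 and 463 without day 9 Eif3m replicate 1, 2 and 3, and 2365 and 2367 without day 13 control replicate 1 and 2, which enter through the shared estimate of spread. With no filter on low counts 1583 genes were called, with DESeq2 1626, and with day 9 fitted alone 3445 (1562 up, 1883 down). Scaling by library totals alone raised the share of rises among called genes from 43.7% to 70.8% and moved the median of all genes from -0.00 to 0.12.

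Targets of p53 rose in day 9 RNA as a group. Of 30 tested, 13 rose, 2 fell and 15 did not pass, and 17 rose and 3 fell within the list, that is, when adjusted over its genes alone (median 0.93, adjusted p = 6.3e-16). This held (adjusted p = 0.0026 with an estimated correlation). Cdkn1a, the cell cycle inhibitor p21, went from 0.131 ± 0.00865 to 7.42 ± 0.864 CPM, a log2 change of 5.79 (SE 0.35), and Eda2r and Phlda3 changed by 3.80 (SE 0.48) and 3.44 (SE 0.59). The list of genes of the integrated stress response, the ATF4 and CHOP programme, rose too: of 32, 8 rose, 1 fell and 23 did not pass, and 11 rose and 1 fell within the list (median 0.40, adjusted p = 4.3e-07, and 0.25 with estimated correlation). Its members Fgf21, a hormone secreted by the stressed liver, and Atf5 changed by 2.81 (SE 0.43) and 1.95 (SE 0.32). Cell cycle genes had a median of 0.35 with 3 of 50 up, 1 down and 7 and 1 within the list (adjusted p = 0.0017, adjusted p = 0.59 with an estimated correlation, and 0.057 without day 9 control replicate 2). The member that fell was Tk1, thymidine kinase, at -0.97 (SE 0.17). The cell cycle median was 0.53, 0.19 and 0.16 without day 9 control replicate 1, control replicate 2 and Eif3m replicate 1.

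Several lists of the translation machinery rose in day 9 RNA. Of 80 cytosolic ribosomal protein genes, 24 rose, 0 fell and 56 did not pass, and 65 rose and 0 fell within the list (median 0.45, adjusted p = 1.6e-25, and 0.052 with estimated correlation). Rps12, Rpl13a and Rps19 changed by 0.90 (SE 0.14), 0.84 (SE 0.13) and 0.75 (SE 0.12). Many of these genes have near-identical pseudogenes elsewhere in the genome, so the exact size of each is uncertain. Ribosome biogenesis factors, which assemble ribosomal subunits in the nucleolus, had 21 of 120 up and 0 down, 30 up within the list (median 0.28, adjusted p = 2.9e-13, and 0.056 with estimated correlation). Examples were Rrp12 at 1.27 (SE 0.21), Nop56 at 1.10 (SE 0.15) and Ddx21 at 0.98 (SE 0.11). Elongation factors and other mRNAs with a terminal oligopyrimidine tract (TOP) had 7 of 19 up, 11 within the list (median 0.44, adjusted p = 4.3e-07, and 0.052 with estimated correlation). Initiation factors outside eIF3 had 5 of 32 up and 0 down, 7 up within the list (median 0.18, adjusted p = 0.0019, and 0.12 with estimated correlation). Among the 14 eIF3 subunit genes, Eif3m fell and Eif3j1 and Eif3j2, near-identical copies that share reads, rose by 0.50 and 0.49. Both calls were lost without any 1 of the 6 day 9 libraries (adjusted p up to 0.15). Adjusted over the list alone 6 rose and 1 fell, and the list test did not pass (median 0.23, adjusted p = 0.28).

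Both lists of lipid synthesis fell in day 9 RNA. Fatty acid and triglyceride synthesis had 11 of 25 genes down and 0 up, 14 down within the list (median -0.71, adjusted p = 3.7e-15, and 0.11 with estimated correlation). Pnpla3, a lipid droplet protein controlled by SREBP1, changed by -3.59 (SE 0.50), Acss2 by -2.08 (SE 0.25) and Thrsp by -2.06 (SE 0.31). Cholesterol synthesis had 8 of 25 down and 0 up, 15 down within the list (median -0.64, adjusted p = 3.4e-10, and 0.43 with estimated correlation). An example was Dhcr7 at -1.30 (SE 0.23). Fatty acid oxidation and PPAR-alpha targets had 6 of 32 down and 1 up, 9 and 1 within the list (median -0.25, adjusted p = 6.1e-04, and 0.59 with estimated correlation). Cytochrome P450 enzymes had 11 of 47 down and 1 up, 18 and 4 within the list (median -0.30, adjusted p = 2.7e-05, and 0.47 with estimated correlation). Bile acid synthesis and transport had 5 of 27 down and 1 up, 9 and 2 within the list (median -0.31, adjusted p = 0.0019, and 0.43 with estimated correlation). An example was the exporter Abcc3 at -1.10 (SE 0.17). Nuclear-encoded respiratory chain genes shifted by a small amount, 6 of 77 down, the same number within the list (median -0.27, adjusted p = 4.3e-08, and 0.27 with estimated correlation). In gluconeogenesis and the urea cycle, G6pc and Pck1, which control glucose output, rose by 2.47 (SE 0.32) and 1.47 (SE 0.29) while Prodh, proline dehydrogenase, fell, at -1.57 (SE 0.12). 2 of 25 rose and 4 fell, 5 and 6 within the list, and the list test did not pass (median -0.21, adjusted p = 0.068). Without day 9 Eif3m replicate 2 the fatty acid oxidation median was -0.16. Under library totals it was -0.12, that of bile acid genes -0.17, of cytochrome P450 enzymes -0.16 and of respiratory chain genes -0.13.

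Markers of other liver cells were compared in day 9 RNA. Genes of stellate cells and fibrosis had 3 of 28 up and 0 down, the same numbers within the list (median 0.37, adjusted p = 3.4e-05, and 0.49 with estimated correlation). An example was Ctgf at 1.40 (SE 0.25). The list median was 0.23 without day 9 Eif3m replicate 1. Among macrophage markers the Kupffer cell genes Cd163, Clec4f and Vsig4 fell, by -2.94 (SE 0.41), -2.03 (SE 0.18) and -1.81 (SE 0.25) on the log2 scale, while 2 others rose, and the list as a whole did not pass (median 0.21, test direction down, adjusted p = 0.81). Sinusoidal endothelial markers had a median of 0.07 (adjusted p = 0.29). Secreted hepatocyte proteins did not pass as a list at day 9 (median -0.14, adjusted p = 0.093), though Apoa2 and Apoc3 fell, at -1.16 (SE 0.16) and -1.01 (SE 0.15) and C8a rose by 1.07 (SE 0.14). Acute phase proteins and interferon-stimulated genes did not pass either, with medians of 0.03 (test direction down, adjusted p = 0.35) and -0.15 (adjusted p = 0.1).

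The day 13 RNA libraries differed from those of day 9 in a way that bears on the day 13 RNA and efficiency values below. Of 5852 genes with at least 10 CPM in day 9 control RNA and footprints, 191 were at least 16-fold lower in control RNA at day 13, and 163 of these were also 16-fold lower in Eif3m RNA. The control RNA of Apoe, an abundant apolipoprotein, was 20746 ± 1524 CPM at day 9 and 274 ± 111 CPM at day 13, while its control footprints were 26623 ± 1921 and 30128 ± 600 CPM. Cebpa, a hepatocyte transcription factor, went from 268 ± 5.35 to 1.38 ± 1.41 CPM in control RNA and from 385 ± 29.2 to 427 ± 25.1 CPM in control footprints. Apoe and Cebpa are examples chosen after their values were seen. Across genes the change between days in RNA had a Pearson r of 0.960 between the 2 siRNA groups and of -0.149 with the footprint change in the controls. Within day 13 both siRNA groups share 1 kit, so the comparison of siRNAs is made inside it, with lower counts for these genes.

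**Figure D2:**
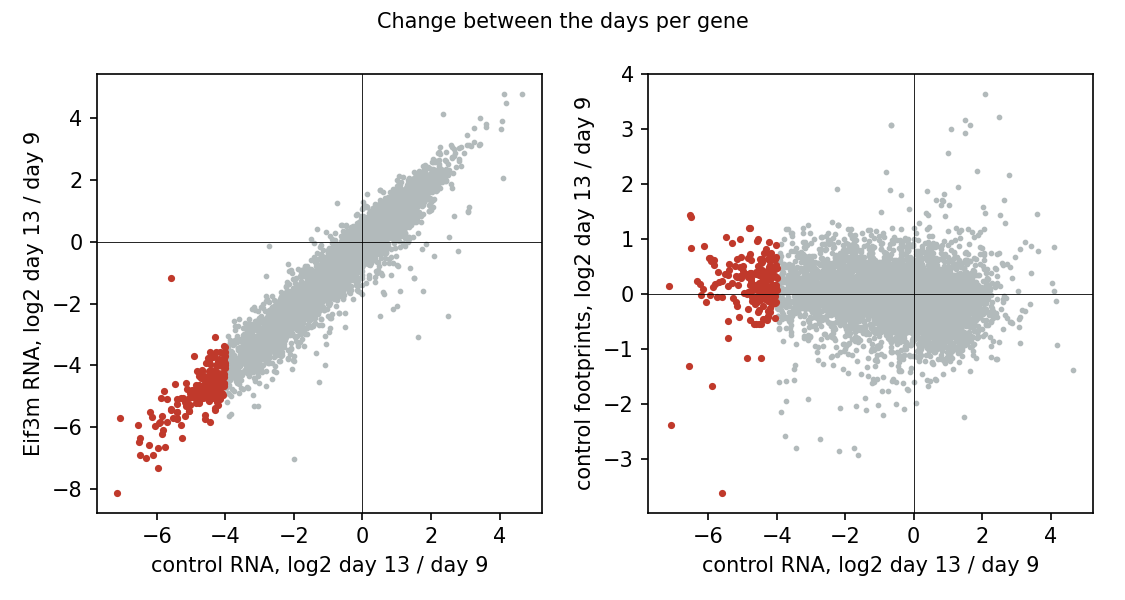
Change between the days for each of 5852 genes, log2 of day 13 over day 9. Control RNA is on the horizontal axis of both panels, Eif3m RNA on the vertical axis of the left panel and control footprints on that of the right panel; the 191 genes at least 16-fold lower in control RNA are red.

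At day 13 (n = 2 per group) the RNA comparison asks the same question after the longer course. Eif3m had the smallest p. Large falls included A1bg, a plasma glycoprotein gene, at -5.73 (SE 0.58), the deiodinase Dio1 at -4.04 (SE 0.52) and the organic anion transporter Slc22a7 at -3.86 (SE 0.46). Large rises included the growth arrest gene Gadd45a at 3.67 (SE 0.25), the NADPH oxidase Nox4 at 3.51 (SE 0.30), Arhgef2 at 3.16 (SE 0.37) and Ifrd1 at 2.81 (SE 0.17). Vomeronasal receptor genes were among the rises. Vmn2r6, with the largest estimate of all, had 0 counts in the controls and 219 with Eif3m siRNA, and Vmn2r4 had 1 and 488. In all, 1002 genes rose and 1623 fell of 16444 (edgeR), and 5082 had an unadjusted p below 0.05 where 822 would by chance. Fitting day 13 alone called 968 genes (527 up, 441 down), and leaving out day 13 control replicate 2 called 4266, Eif3m replicate 1 1602 and Eif3m replicate 2 1336. The share of rises, 38.2%, became 49.1% with DESeq2 size factors, 47.5% with DESeq2, 48.4% with a mean of at least 5 CPM, 54.4% with the day alone and 59.7% with library totals, and the median of all genes was -0.16 with TMM, -0.07 with DESeq2 size factors and 0 with library totals.

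Ribosomal genes were higher with Eif3m siRNA in day 13 RNA too. Of 80 ribosomal protein genes, 62 rose, 0 fell and 18 did not pass, and 70 rose within the list (median 1.08, adjusted p = 4.1e-60), which held (adjusted p = 0.013 with an estimated correlation). Rpl12 went from 75.2 ± 11.8 to 328 ± 102 CPM, a log2 change of 2.12 (SE 0.21), and Rps12, Rpl23 and Rps6 changed by 1.86 (SE 0.18), 1.74 (SE 0.20) and 1.72 (SE 0.14). Reads shared with near-identical copies leave each size uncertain. Among the members that did not pass, Fau and Rpl36 are transcripts nearly missing from the day 13 RNA, at 3.06 and 0.357 CPM in the controls against 219 and 79.1 CPM at day 9, a pair chosen after their values were seen. Ribosome biogenesis factors had 38 of 120 up and 0 down, 47 up within the list (median 0.47, adjusted p = 1.1e-16, and 0.02 with estimated correlation). Examples were Nop56 at 1.65 (SE 0.19), the nucleolar protein gene Npm1 at 1.64 (SE 0.17) and Mrto4 at 1.51 (SE 0.20). TOP mRNAs had 12 of 19 up, the same number within the list (median 0.73, adjusted p = 7.0e-12, and 0.017 with estimated correlation). Examples were Eef1b2 at 1.72 (SE 0.14) and Pabpc1, the poly(A) binding protein, at 1.01 (SE 0.16). Initiation factors outside eIF3 had 12 of 32 up and 1 down, 14 and 1 within the list (median 0.41, adjusted p = 1.5e-07, and 0.02 with estimated correlation). Eif4g2 and Eif5 changed by 1.29 (SE 0.19) and 1.20 (SE 0.16), and the member that fell was Eif4ebp2, an inhibitor of cap binding, at -1.31 (SE 0.23). Of the eIF3 subunit genes 7 rose and only Eif3m fell, 10 rose within the list (median 0.50, adjusted p = 0.0037, and 0.076 with estimated correlation). Examples were Eif3e at 0.72 (SE 0.15) and the pair Eif3j1 and Eif3j2, which share reads, at 0.88 (SE 0.16) and 0.88 (SE 0.16). The eIF3 median was 0.31 without day 13 control replicate 2.

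Targets of p53 had 7 of 30 up and 1 down in day 13 RNA, 8 and 2 within the list (median 0.19, adjusted p = 0.006, and 0.076 with estimated correlation). Examples were Eda2r at 4.08 (SE 0.62) and Trp53inp1 at 2.55 (SE 0.32). The member that fell was Pltp, phospholipid transfer protein, at -2.46 (SE 0.32). Cdkn1a was near the floor in day 13 RNA, at 0.0238 CPM in the controls and 0.0939 CPM with Eif3m siRNA, while its footprints rose on that day. The integrated stress response list did not pass (median -0.19, test direction up, adjusted p = 0.19), with 5 of 32 up and 2 down, among the risen Ddit3 at 2.75 (SE 0.39). The p53 median was 0.31 without day 9 Eif3m replicate 1 or 3, 0.45 and 0.02 without day 13 control replicate 1 and 2, 0.09 and 0.11 without day 13 Eif3m replicate 1 and 2, 0.11 with the replicate block and 0.38 with library totals.

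Several lists of hepatocyte genes were lower in day 13 RNA. Fatty acid and triglyceride synthesis had 15 of 25 down and 0 up, 20 down within the list (median -1.18, adjusted p = 4.4e-13, and 0.076 with estimated correlation). Examples were Thrsp at -3.57 (SE 0.43), Fasn at -2.65 (SE 0.31) and Acacb at -2.60 (SE 0.40). Cholesterol synthesis had 9 of 25 down, 13 within the list (median -0.90, adjusted p = 3.4e-06, and 0.46 with estimated correlation). For fatty acid oxidation and PPAR-alpha targets the counts were 13 of 32 down and 1 up, 14 and 1 within the list (median -0.51, adjusted p = 4.3e-04, and 0.55 with estimated correlation). Bile acid genes had 9 of 27 down and 1 up, 11 and 1 within the list (median -0.69, adjusted p = 6.8e-04, and 0.25 with estimated correlation). Examples were Abcc3 at -1.65 (SE 0.21) and Cyp27a1 at -1.47 (SE 0.24). Cytochrome P450 enzymes had 14 of 47 down and 3 up, 20 and 4 within the list (median -0.37, adjusted p = 0.023, and 0.64 with estimated correlation). That call was lost with library totals (adjusted p = 0.096) and without day 9 control replicate 2 or 3 or day 13 control or Eif3m replicate 2 (adjusted p = 0.054, 0.057, 0.12 and 0.44). Secreted hepatocyte proteins had 14 of 52 down and 2 up, 18 and 3 within the list (median -0.28, adjusted p = 0.026, and 0.68 with estimated correlation). The list call was lost with DESeq2 size factors (adjusted p = 0.11), with library totals (adjusted p = 0.37), without any 1 of the 6 day 9 libraries (adjusted p = 0.073 to 0.099) and without day 13 control replicate 1 (adjusted p = 0.11) or Eif3m replicate 2 (adjusted p = 0.37). Its members Apoa5, Apoc3 and Apoa4 fell, at -2.06 (SE 0.34), -1.57 (SE 0.19) and -1.26 (SE 0.20). Gluconeogenesis and urea cycle genes and respiratory chain genes did not pass (median -0.37, adjusted p = 0.19, and median -0.04, test direction up, adjusted p = 0.99), with medians of -0.14 and 0.16 under library totals. Without day 13 control replicate 1 the median was -0.78 for fatty acid synthesis, -0.30 for bile acid genes and -0.29 for fatty acid oxidation. Without day 13 Eif3m replicate 1 it was -1.40 for cholesterol synthesis, -0.58 for cytochrome P450 enzymes and -0.44 for secreted proteins, and -0.14 for the last without Eif3m replicate 2. Each list called here lost its call with an estimated correlation.

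Several lists of inflammatory genes and markers of other cells were lower in day 13 RNA. Acute phase genes had 16 of 31 down and 1 up, 19 and 2 within the list (median -0.86, adjusted p = 5.6e-08, and 0.15 with estimated correlation). An example was Lcn2, lipocalin 2, at -3.31 (SE 0.48). Interferon-stimulated genes had 16 of 44 down and 0 up, 19 down within the list (median -0.87, adjusted p = 3.0e-07, and 0.16 with estimated correlation). Examples were Zbp1 at -4.05 (SE 0.76), Igtp at -1.99 (SE 0.32) and Usp18 at -1.71 (SE 0.23). Macrophage markers had 13 of 21 down and 1 up, 14 and 1 within the list (median -1.32, adjusted p = 3.0e-07, and 0.02 with estimated correlation). An example was Clec4f at -2.20 (SE 0.24). Sinusoidal endothelial markers had 11 of 20 down, 14 within the list (median -0.77, adjusted p = 1.7e-06, and 0.11 with estimated correlation). Examples were Lyve1 at -1.87 (SE 0.37) and Cdh5, vascular cadherin, at -1.51 (SE 0.20). Stellate cell and fibrosis genes had 8 of 28 down, 9 within the list (median -0.74, adjusted p = 9.3e-04, and 0.5 with estimated correlation). An example was Col1a2 at -1.81 (SE 0.30). This call was lost without day 13 control replicate 1 (median -0.33, adjusted p = 0.072). Erythroid and blood genes had 6 of 11 down, 8 within the list (median -2.13, adjusted p = 3.3e-05, and 0.31 with estimated correlation), with medians of -1.11 and -3.35 without day 13 control and Eif3m replicate 1. Neutrophil markers had 4 of 8 down, 5 within the list (median -2.04, adjusted p = 0.016, and 0.15 with estimated correlation), a call lost without day 13 control replicate 1 or 2 or Eif3m replicate 1 (adjusted p = 0.086, 0.11 and 0.49). The neutrophil median was -2.67 without day 9 control replicate 1, -1.31 without any other 1 day 9 library, and -3.76 and -5.21 without day 13 Eif3m replicate 1 and 2.

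Footprints at day 9 (n = 3 per group) ask which messages ribosomes occupied more or less with Eif3m siRNA. Cdkn1a rose most, from 0.862 ± 0.335 to 31.8 ± 8.94 CPM, a log2 change of 5.15 (SE 0.29). Other large rises were those of Ifrd1 at 3.69 (SE 0.19), Igfbp1 at 3.29 (SE 0.38) and the histamine receptor gene Hrh3 at 2.61 (SE 0.34), whose RNA had at most 0.5 counts in any library, so that no message was measured. Cyp17a1 fell most, at -4.72 (SE 0.76), and the Kupffer cell receptor Cd163, Acacb and the melanin enzyme gene Dct changed by -3.63 (SE 0.35), -2.94 (SE 0.45) and -2.74 (SE 0.25). In all 835 genes rose and 965 fell of 12213 tested (edgeR), and 3522 had an unadjusted p below 0.05 where 611 would by chance. Without day 9 control replicate 2, 1129 genes were called, and with library totals 2742, of which 2289 rose and 453 fell, so that the share of rises went from 46.4% to 83.5% and the median of all genes from 0.02 to 0.25.

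In day 9 footprints targets of p53 had 14 of 25 up and 2 down, 14 and 4 within the list (median 0.84, adjusted p = 1.8e-10), which held (adjusted p = 0.024 with an estimated correlation). Phlda3 and the nuclease Aen changed by 3.54 (SE 0.40) and 2.38 (SE 0.15). Integrated stress response genes had 9 of 29 up and 1 down, 12 and 2 within the list (median 0.36, adjusted p = 3.5e-05, and 0.13 with estimated correlation). Examples were Ddit3 at 3.54 (SE 0.42), Fgf21 at 3.29 (SE 0.45) and Trib3 at 2.01 (SE 0.35). Ribosomal protein genes had 61 of 77 up and 0 down, 69 up within the list (median 0.78, adjusted p = 2.3e-35, and 0.21 with estimated correlation). Examples were Rps12 at 2.01 (SE 0.36), Rps27a at 1.75 (SE 0.31) and Rpl13a at 1.51 (SE 0.17), sizes again uncertain from shared reads. Ribosome biogenesis factors had 40 of 120 up and 1 down, 56 and 1 within the list (median 0.43, adjusted p = 9.2e-14, and 0.15 with estimated correlation). Examples were Rrp12 at 1.57 (SE 0.19) and Nop58 at 1.19 (SE 0.23). TOP mRNAs had 8 of 19 up, 11 within the list (median 0.58, adjusted p = 2.9e-07, and 0.25 with estimated correlation). Other initiation factors had 8 of 32 up and 1 down, the same numbers within the list (median 0.25, adjusted p = 0.012, and 0.25 with estimated correlation), where Eif4ebp2 fell, at -1.47 (SE 0.17). Of the eIF3 subunit genes, 6 rose and Eif3m fell, 7 rose within the list, with Eif3c at 0.64 (SE 0.13), and the list test did not pass (median 0.37, adjusted p = 0.18). Cytosolic aminoacyl-tRNA synthetases did not pass as a list (median 0.15, adjusted p = 0.26), with 2 of 20 up and 1 down, the same numbers within the list.

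**Figure D3:**
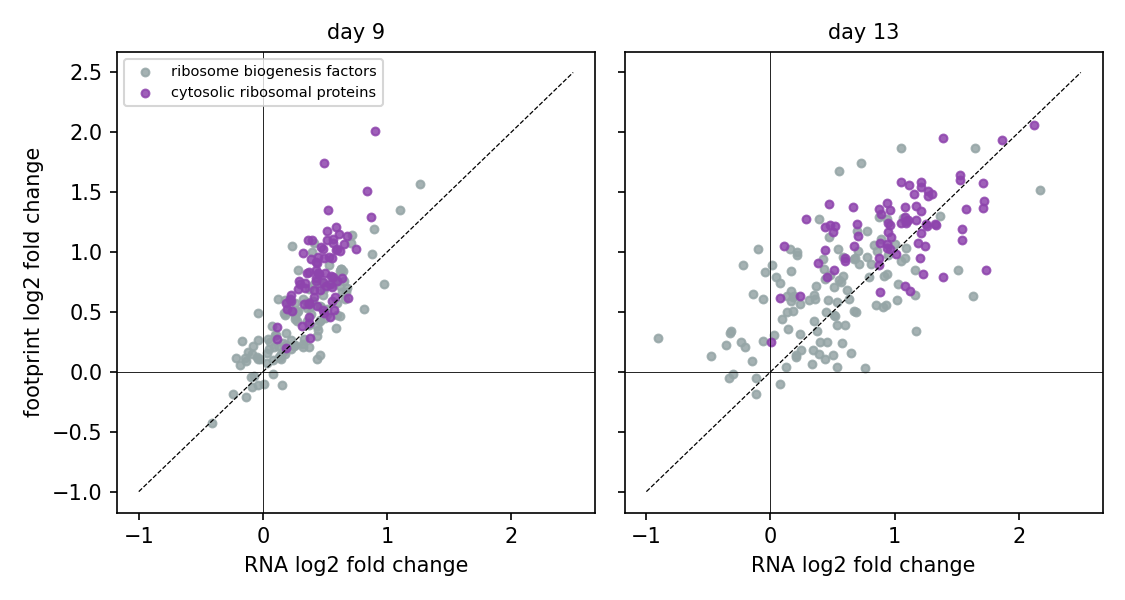
Log2 change with Eif3m siRNA in footprints (vertical axis) against RNA (horizontal axis) for each ribosomal protein gene and ribosome biogenesis factor, day 9 on the left and day 13 on the right; the dashed line marks equal change. List medians at day 9 are 0.45 in RNA and 0.78 in footprints for ribosomal proteins, and 1.08 and 1.23 at day 13.

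Several lists of lipid, drug and plasma protein genes fell in day 9 footprints. Fatty acid and triglyceride synthesis had 17 of 25 down and 0 up, 19 and 1 within the list (median -0.85, adjusted p = 7.4e-14, and 0.049 with estimated correlation). An example was Fasn at -2.20 (SE 0.32). Cholesterol synthesis had 12 of 25 down, 14 within the list (median -0.86, adjusted p = 9.6e-10, and 0.34 with estimated correlation). An example was Insig1 at -1.59 (SE 0.25). Cytochrome P450 enzymes had 20 of 46 down and 4 up, 23 and 5 within the list (median -0.41, adjusted p = 1.5e-05, and 0.15 with estimated correlation). Bile acid genes had 14 of 27 down and 1 up, 15 and 1 within the list (median -0.38, adjusted p = 4.3e-06, and 0.067 with estimated correlation). Examples were Akr1d1 at -1.10 (SE 0.14) and the transporter Slco1b2 at -0.99 (SE 0.15). Secreted hepatocyte proteins had 16 of 52 down and 4 up, 21 and 5 within the list (median -0.26, adjusted p = 5.2e-05, and 0.3 with estimated correlation). Examples were Apoa2 at -1.10 (SE 0.12) and Ttr, transthyretin, at -0.82 (SE 0.12). Acute phase genes had 8 of 31 down and 1 up, 9 and 1 within the list (median -0.23, adjusted p = 0.012, and 0.33 with estimated correlation), a median that became 0.00 with library totals and a call lost without day 9 control replicate 3 (adjusted p = 0.078). The member that rose was Hpx, hemopexin, at 1.40 (SE 0.12). Gluconeogenesis and urea cycle genes had 9 of 25 down and 3 up, 14 and 4 within the list (median -0.32, adjusted p = 0.011, and 0.39 with estimated correlation), a call lost without day 9 Eif3m replicate 1 (adjusted p = 0.16). G6pc again rose, by 2.20 (SE 0.24), while Ass1 changed by -0.96 (SE 0.15). For fatty acid oxidation and PPAR-alpha targets 6 of 31 fell and 1 rose, 7 and 3 within the list (median -0.18, adjusted p = 0.011, and 0.61 with estimated correlation). The median was 0.05 with library totals, and the call was lost without day 9 control or Eif3m replicate 2 (adjusted p = 0.072 and 0.2). Respiratory chain genes had 9 of 77 down, the same number within the list (median -0.15, adjusted p = 2.9e-04, and 0.25 with estimated correlation), with a median of 0.08 under library totals. Those medians under library totals lie below the 0.25 median of all genes. Library totals also gave medians of -0.03 for secreted proteins, -0.09 for gluconeogenesis, -0.15 for bile acid genes and -0.18 for cytochrome P450 enzymes. Without day 9 Eif3m replicate 1 the P450 and fatty acid oxidation medians were -0.27 and -0.29, without Eif3m replicate 2 the latter was -0.08, and without control replicate 3 that of gluconeogenesis was -0.21.

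Stellate cell and fibrosis genes rose in day 9 footprints: 10 of 28 rose and 0 fell, 12 rose within the list (median 0.50, adjusted p = 2.2e-09), which held (adjusted p = 0.024 with an estimated correlation). Ctgf, Col1a1, Col3a1 and Vim changed by 1.77 (SE 0.22), 1.37 (SE 0.18), 1.15 (SE 0.15) and 1.11 (SE 0.16). Macrophage markers went both ways, with Clec4f at -1.68 (SE 0.15) and the lysozyme gene Lyz2, which shares reads with Lyz1, at 1.55 (SE 0.14). 3 of 18 rose and 3 fell, and the list did not pass (median 0.17, test direction down, adjusted p = 0.96). The endothelial marker Lyve1 rose by 1.25 (SE 0.20), with the list at a median of 0.17 (adjusted p = 0.067). Interferon-stimulated genes had 6 of 39 down and 3 up and did not pass as a list (median -0.26, adjusted p = 0.22).

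At day 13 (n = 2 per group) stress genes were again among the large footprint rises. Cdkn1a went from 1.40 ± 0.477 to 64.3 ± 7.67 CPM, a log2 change of 5.53 (SE 0.43), and Ifrd1, Trib3 and Gadd45a changed by 4.70 (SE 0.36), 4.83 (SE 0.64) and 4.14 (SE 0.34). Gdf15, a stress-induced hormone, had 3 counts in the controls and 264 with Eif3m siRNA, a ratio of 35.0 (95% counting interval 11.8 to 171), and Ddit3 had 2 and 115, a ratio of 22.8 (95% counting interval 6.18 to 191). Beside Eif3m, the transporter gene Slc22a26 fell, at -4.05 (SE 0.37). In all 748 genes rose and 767 fell of 12213 (edgeR), and 3084 had an unadjusted p below 0.05 where 611 would by chance. Leaving out day 13 control replicate 1 or 2 gave 699 or 747 called genes and leaving out Eif3m replicate 2 gave 429. Library totals gave 2355, of which 2002 rose and 353 fell, raising the share of rises from 49.4% to 85.0% and the median of all genes from 0.02 to 0.34.

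Ribosomal protein genes had the highest list median in day 13 footprints among the 34 lists tested there, 1.23: 64 rose, 0 fell and 13 did not pass, and 73 of 77 rose within the list (adjusted p = 4.6e-57, adjusted p = 0.09 with an estimated correlation). Their summed level was 6320 ± 1302 CPM in the controls and 14112 ± 203 CPM with Eif3m siRNA. Rpl12, Rpl13a and Rps20 changed by 2.06 (SE 0.26), 1.96 (SE 0.21) and 1.65 (SE 0.30). Ribosome biogenesis factors had 48 of 120 up and 0 down, 62 up within the list (median 0.64, adjusted p = 2.5e-18, and 0.09 with estimated correlation). Examples were Nhp2 at 1.87 (SE 0.26), Nop56 at 1.87 (SE 0.33) and Exosc2 at 1.74 (SE 0.35). Mitochondrial ribosomal proteins had 12 of 76 up and 1 down, 18 and 1 within the list (median 0.36, adjusted p = 6.1e-07, and 0.09 with estimated correlation). TOP mRNAs had 8 of 19 up, 11 up and 1 down within the list (median 0.53, adjusted p = 1.9e-05, and 0.26 with estimated correlation). Other initiation factors had 6 of 32 up and 1 down, 10 and 1 within the list (median 0.38, adjusted p = 3.2e-04, and 0.09 with estimated correlation). An example was Eif4g2 at 1.55 (SE 0.17). Of the eIF3 subunit genes 6 rose and Eif3m fell, 9 rose within the list (median 0.46, adjusted p = 0.0072, and 0.13 with estimated correlation, a call lost without day 13 control replicate 1 at adjusted p = 0.057). Examples were Eif3i at 1.40 (SE 0.20) and Eif3g at 1.15 (SE 0.16). Aminoacyl-tRNA synthetases had 5 of 20 up and 1 down, 7 and 2 within the list, and did not pass as a list (median 0.34, adjusted p = 0.065). Targets of p53 had 11 of 25 up and 1 down, 12 and 1 within the list (median 1.10, adjusted p = 1.8e-10, and 0.055 with estimated correlation), and integrated stress response genes 7 of 29 up and 2 down, 9 and 2 within the list (median 0.39, adjusted p = 4.7e-04, and 0.11 with estimated correlation). An example was Atf5 at 2.85 (SE 0.23).

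Several lists of plasma protein, sterol and inflammatory genes fell in day 13 footprints. Secreted hepatocyte proteins had 24 of 52 down and 2 up, 28 and 4 within the list (median -0.50, adjusted p = 1.9e-09, and 0.11 with estimated correlation). Examples were Alb, albumin, at -0.97 (SE 0.17) and Apoa5 at -1.50 (SE 0.19). Acute phase genes had 16 of 31 down and 1 up, 19 and 1 within the list (median -0.92, adjusted p = 2.5e-10, and 0.055 with estimated correlation). Examples were Orm2 and Orm1, close copies, at -1.76 (SE 0.22) and -1.55 (SE 0.18). Interferon-stimulated genes had 11 of 39 down, 15 within the list (median -0.74, adjusted p = 9.5e-08, and 0.16 with estimated correlation). An example was Iigp1 at -1.89 (SE 0.20). Fatty acid and triglyceride synthesis had 15 of 25 down, 18 within the list (median -0.74, adjusted p = 6.2e-13, and 0.055 with estimated correlation), and cholesterol synthesis 6 of 25 down, 12 within the list (median -0.98, adjusted p = 4.5e-10, and 0.27 with estimated correlation). An example was Insig1 at -2.25 (SE 0.33). Bile acid genes had 9 of 27 down and 2 up, 12 and 2 within the list (median -0.53, adjusted p = 3.5e-07, and 0.055 with estimated correlation). An example was the bile acid importer Slc10a1 at -1.24 (SE 0.17). Cytochrome P450 enzymes had 12 of 46 down and 1 up, 17 and 1 within the list (median -0.24, adjusted p = 6.6e-04, and 0.15 with estimated correlation), with a median of 0.08 under library totals. The member that rose was Cyp2u1 at 2.42 (SE 0.32). Fatty acid oxidation and PPAR-alpha targets had 7 of 31 down, 8 within the list (median -0.26, adjusted p = 0.0012, and 0.54 with estimated correlation), a median of 0.06 under library totals and a call lost without day 13 control replicate 1 (adjusted p = 0.07). Unfolded protein response genes had 6 of 29 down and 2 up, 10 and 4 within the list (median -0.33, adjusted p = 0.011, and 0.49 with estimated correlation). An example was the chaperone Dnajb9 at -1.91 (SE 0.29). That list call was lost with library totals and without day 13 control or Eif3m replicate 1 (adjusted p = 0.23, 0.084 and 0.055). Stellate cell and fibrosis genes had 6 of 28 down and 0 up, 7 and 1 within the list (median -0.26, adjusted p = 4.7e-04, and 0.09 with estimated correlation). An example was Col1a1 at -2.07 (SE 0.22). The list had a median of 0.07 under library totals, where the median of all genes is 0.34. Macrophage markers had 8 of 18 down and 1 up, 9 and 1 within the list (median -0.68, adjusted p = 2.8e-04, and 0.26 with estimated correlation). Clec4f changed by -1.69 (SE 0.21) and the integrin gene Itgam by 1.35 (SE 0.21). Sinusoidal endothelial markers did not pass in footprints (median -0.03, 0.29 under library totals, adjusted p = 0.89). Library totals gave medians of -0.18 for secreted proteins, -0.20 for bile acid genes, -0.01 for the unfolded protein response and -0.36 for macrophages. Medians without day 13 control replicate 1 were -0.12 for fatty acid oxidation and -0.17 for the unfolded protein response, those without control replicate 2 -0.46 for fatty acid oxidation and -0.44 for macrophages, and that of cholesterol synthesis was -0.61 without Eif3m replicate 2.

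**Figure D4:**
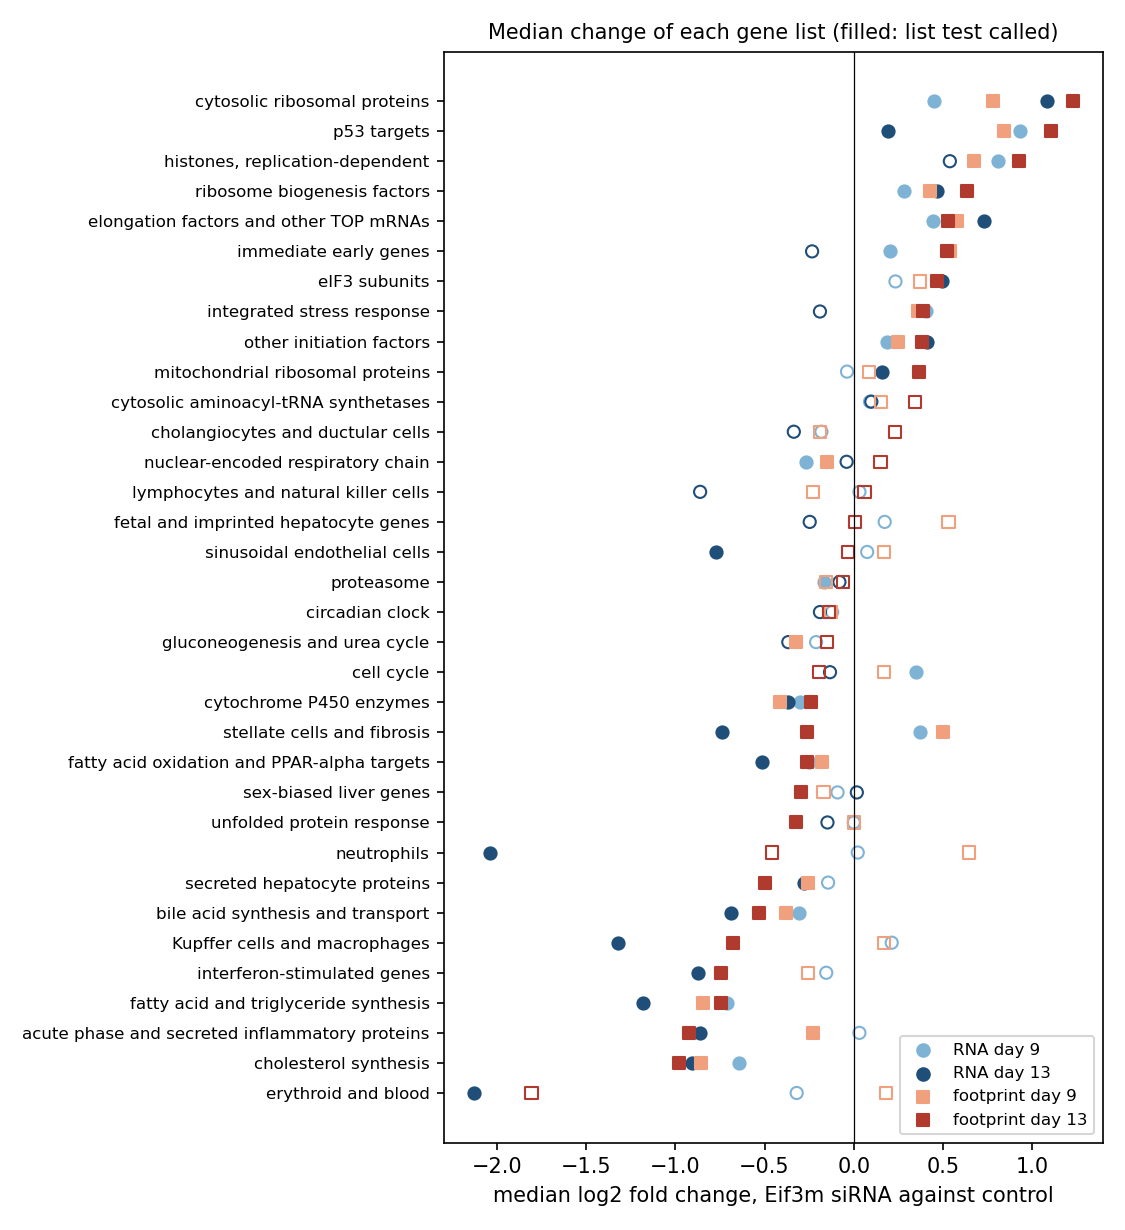
Median log2 change with Eif3m siRNA of each list, for RNA (circles) and footprints (squares) at both days; filled symbols mark lists that passed the list test at its preset correlation. Medians of ribosomal protein genes lie between 0.45 and 1.23 and those of cholesterol synthesis between -0.98 and -0.64; with library totals some medians near 0 change sign.

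Translational efficiency, footprints relative to RNA of the same animals, asks whether ribosome occupancy moved beyond the message. At day 13 Farsa, a subunit of phenylalanyl-tRNA synthetase, rose by 2.07 (SE 0.36), and Gas5, a noncoding snoRNA host gene, and Pabpc1 fell, at -2.22 (SE 0.38) and -2.14 (SE 0.36) (adjusted p = 0.030 for each). Control and Eif3m CPM were 4.36 and 1.47 in RNA and 29.5 and 49.9 in footprints for Farsa. They were 661 and 1333, then 182 and 88.8, for Pabpc1 and 25.1 and 175, then 43.5 and 69.8, for Gas5. These were the calls among 14236 genes tested at day 13, 1 up and 2 down (edgeR), and 1424 had an unadjusted p below 0.05 where 712 would by chance. At day 9 edgeR called 0 genes and DESeq2 2, with 692 at an unadjusted p below 0.05. Chance would give 712, and other divisions of the animals gave 114 to 258. Paired by animal, the block fit called 8 genes at day 9 (4 up, 4 down) and 12 at day 13 (6 up, 6 down). Limma on paired log ratios called 0 and 93. No gene was called without day 13 Eif3m replicate 2 (adjusted p = 0.32 for each of the 3). Without day 13 Eif3m replicate 1 the adjusted p was 0.051 for Farsa, 0.12 for Gas5 and 0.18 for Pabpc1, and without day 9 Eif3m replicate 1 it lay between 0.05 and 0.051. The calls of Farsa and Gas5 were lost without day 13 control replicate 1 (adjusted p = 0.15 and 0.18), and those of Farsa and Pabpc1 without day 9 Eif3m replicate 3 (adjusted p = 0.095 for both) and with day 13 fitted alone (adjusted p = 0.42 and 0.054). Pabpc1 was also lost with limma (adjusted p = 0.075). The count was 5 without day 9 control replicate 2, 1 without day 9 Eif3m replicate 1 or 3, and 438 without day 13 control replicate 2. At day 9 the count was 5 without day 13 control replicate 1 or 2. The median of all genes at day 13 was 0.13.

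The list test passed for 9 lists at day 9 and 6 at day 13, and for none of them with an estimated correlation. Ribosomal protein genes rose in efficiency at day 9 (median 0.36, adjusted p = 3.6e-15, and 0.49 with estimated correlation) with 0 of 79 genes called and 1 up within the list. Sinusoidal endothelial markers rose at day 13 (median 0.71, adjusted p = 1.5e-09, and 0.13 with estimated correlation), with 0 of 20 called and 3 up within the list, and with their RNA lower and their footprints not past the test. Secreted hepatocyte proteins fell at day 9 (median -0.11, adjusted p = 0.0015, and 0.59 with estimated correlation) and at day 13 (median -0.20, adjusted p = 3.9e-05, and 0.41 with estimated correlation, lost without day 13 control replicate 2 at adjusted p = 0.19). Acute phase genes fell at day 9 (median -0.22, adjusted p = 0.0068, and 0.49 with estimated correlation) and mitochondrial ribosomal proteins rose (median 0.13, adjusted p = 0.0015, and 0.47 with estimated correlation). Replication-dependent histones fell at day 9 (median -0.37, adjusted p = 0.002, and 0.47 with estimated correlation), with a median of 0.70 at day 13, not called. This list had 22 genes tested here and 9 in RNA, so many had little RNA to divide by. Kupffer cell and macrophage markers rose in efficiency at day 9 (median 0.28, adjusted p = 0.022, and 0.49 with estimated correlation), a call lost without day 9 control replicate 2 or 3 or Eif3m replicate 2 or 3 (adjusted p = 0.055, 0.058, 0.23 and 0.057). They rose at day 13 (median 0.60, adjusted p = 0.0045, and 0.41 with estimated correlation), lost without day 13 control or Eif3m replicate 1 (adjusted p = 0.058 and 0.16). For initiation factors outside eIF3 at day 13 the median, 0.01, and the test, which gave a fall at adjusted p = 0.045 (adjusted p = 0.41 with an estimated correlation), differed in sign. The median was -0.04 with DESeq2 size factors and 0.20 with library totals. The call was lost with the animal as a block (adjusted p = 0.15), with library totals (adjusted p = 0.31) and without any 1 of the 4 day 13 animals (control replicate 1 and 2, adjusted p = 0.38 and 0.13, and Eif3m replicate 1 and 2, adjusted p = 0.22 and 0.3). Under library totals the secreted protein median was -0.00 at day 9 and -0.01 at day 13, that of acute phase genes -0.11 and of mitochondrial ribosomal proteins 0.24, where the median of all genes was 0.13 and 0.34. Single animals moved other medians of the day 9 efficiency lists. Ribosomal proteins had 0.54 and 0.20 and acute phase genes -0.11 and -0.12 without day 9 control replicate 3 and Eif3m replicate 1, macrophages 0.14 and 0.11 without control replicate 1 and Eif3m replicate 3, and histones -0.23 without Eif3m replicate 2. At day 13 macrophages had 0.34 without control replicate 1, secreted proteins -0.10 and -0.02 without control replicate 2 and Eif3m replicate 1, and initiation factors -0.00 and -0.06 without control replicate 1 and 2 and 0.00 and 0.03 without Eif3m replicate 1 and 2. Weaker rises at day 9 were those of TOP mRNAs (median 0.16, adjusted p = 0.049, and 0.75 with estimated correlation) and ribosome biogenesis factors (median 0.11, adjusted p = 0.023, and 0.75 with estimated correlation), beside a fall of bile acid genes (median -0.06, adjusted p = 0.03, and 0.49 with estimated correlation, 0.04 under library totals). The TOP call was lost with the animal as a block (adjusted p = 0.08), without day 9 control replicate 1 or 2 or Eif3m replicate 1 or 3 (adjusted p = 0.47, 0.24, 0.23 and 0.067) and without either day 13 Eif3m animal (adjusted p = 0.067), with medians of 0.05, 0.36, 0.10 and 0.28 without day 9 control replicate 1 and 3 and Eif3m replicate 1 and 2. The biogenesis call was lost without day 9 control replicate 1 or 3, Eif3m replicate 2 or day 13 Eif3m replicate 2 (adjusted p = 0.075, 0.058, 0.12 and 0.051), and the bile acid call without day 9 control or Eif3m replicate 1 or 2 (adjusted p = 0.051 to 0.089), with a median of -0.02 without either replicate 2. At day 13 TOP mRNAs fell (median -0.31, adjusted p = 0.0033, and 0.65 with estimated correlation), lost without control or Eif3m replicate 2 (medians 0.02 and -0.17, adjusted p = 0.69 and 0.39). Targets of p53 rose (median 0.29, adjusted p = 0.045, and 0.3 with estimated correlation), lost with library totals or the animal as a block (adjusted p = 0.065 and 0.053) and without any 1 of the 4 day 13 animals (adjusted p = 0.094 to 0.23), with a median of 0.57 without control or Eif3m replicate 1.

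The difference between the days asks whether the siRNA effect at day 13 departed from day 9. It did for 202 genes in RNA (56 higher, 146 lower at day 13) and for 100 in footprints (27 higher, 73 lower). In RNA the share higher at day 13, 27.7%, became 42.5% with DESeq2 size factors, 47.4% with a mean of at least 5 CPM, 44.4% with DESeq2 and 9.84% with the replicate block. In footprints the effect on Col1a1, type I collagen, differed by -3.44 (SE 0.28) from day 9, on Col3a1 by -2.28 (SE 0.24) and on Lyz2 by -2.27 (SE 0.24). Col1a1 footprints were 12.3 CPM in day 9 controls and 31.9 with Eif3m siRNA, against 104 and 25.5 at day 13. Those of Col3a1 were 42.5 and 94.6, then 203 and 94.5 CPM, and of Lyz2 26.3 and 77.4, then 72.4 and 44.0 CPM. The effect on the stellate cell and fibrosis list was lower at day 13 in footprints (median -0.82, adjusted p = 1.4e-23), with 8 of 28 genes called and 12 within the list. This held (adjusted p = 0.0081 with an estimated correlation). In RNA the median was -1.25 (adjusted p = 1.2e-11, and 0.16 with estimated correlation). Ribosomal protein genes rose more at day 13, in RNA (median 0.56, adjusted p = 2.8e-28, and 0.054 with estimated correlation), where 10 of 80 were called and 38 within the list, and in footprints (median 0.40, adjusted p = 1.1e-08, and 0.51 with estimated correlation), where 0 were called. Macrophage marker effects were lower at day 13 in RNA (median -1.47, adjusted p = 2.4e-08, and 0.054 with estimated correlation). They were in footprints too (median -0.80, adjusted p = 2.5e-06, and 0.32 with estimated correlation). So were those on interferon-stimulated genes (median -0.71, adjusted p = 2.2e-06, and 0.21 with estimated correlation in RNA). Their footprint median was -0.60 (adjusted p = 7.7e-08, and 0.32 with estimated correlation). The ribosomal protein footprint median was 0.19 without day 9 control replicate 3 and 0.21 and 0.66 without day 13 control replicate 1 and 2. Without day 13 Eif3m replicate 2 the footprint medians of macrophages and interferon-stimulated genes were -0.52 and -0.38, and without day 13 control replicate 1 the RNA median of the fibrosis list was -0.75. In efficiency 4 lists passed, none with an estimated correlation. The effect on ribosomal proteins was lower at day 13 (median -0.28, adjusted p = 2.9e-06, and 0.98 with estimated correlation). Its medians were -0.16, -0.50 and -0.10 without day 9 control replicate 1 and 3 and Eif3m replicate 1, and -0.42 without day 13 control replicate 1. The call was lost without day 13 control or Eif3m replicate 2 (medians 0.15 and -0.06). The effect on TOP mRNAs was lower too (median -0.38, adjusted p = 2.9e-06, and 0.42 with estimated correlation), lost without the same 2 animals (medians 0.11 and -0.23). Effects on endothelial markers were higher (median 0.68, adjusted p = 2.4e-07, and 0.29 with estimated correlation). Those on other initiation factors were lower (median -0.15, adjusted p = 0.036, and 0.42 with estimated correlation). That call was lost with library totals, the animal as a block or any 1 day 13 animal left out. It was also lost without day 9 control replicate 2 or Eif3m replicate 2 or 3 (adjusted p = 0.076, 0.069 and 0.11). Medians ran from -0.22 to -0.01.

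**Figure D5:**
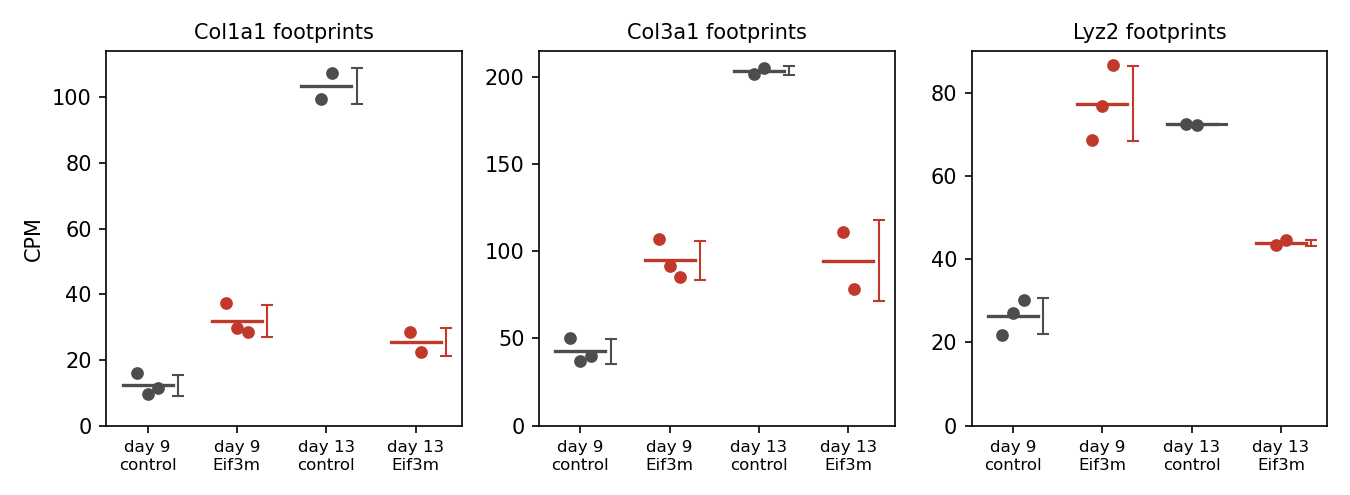
Footprint levels of Col1a1, Col3a1 and Lyz2 in CPM. Each point is 1 library, the line is the group mean and the bar its SD; Col1a1 means are 12.3 and 31.9 CPM at day 9 and 104 and 25.5 CPM at day 13 for control and Eif3m siRNA.

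These counts depended on single libraries. In RNA, 34, 18 and 55 genes differed between days without day 9 control replicate 1, 2 and 3, 19, 77 and 16 without day 9 Eif3m replicate 1, 2 and 3, 687 and 2065 without day 13 control replicate 1 and 2, and 125 and 0 without day 13 Eif3m replicate 1 and 2. With no filter 1034 did, with DESeq2 728. In footprints the count was 52 without day 9 control replicate 2, 172 and 59 without day 9 Eif3m replicate 1 and 3, 43 and 24 without day 13 control replicate 1 and 2, 65 and 7 without day 13 Eif3m replicate 1 and 2, and 242 with no filter. For translational efficiency edgeR called 0 genes between days, with 765 at an unadjusted p below 0.05, DESeq2 2, limma 9, and the fit with the animal as a block 5; 59 were called without day 13 control replicate 2, 2 without day 13 control replicate 1, and 1 without day 9 control replicate 2 or day 13 Eif3m replicate 1.

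RNA and footprint changes, measured in the same animals, went together across genes. At day 9 the log2 changes of 11970 genes had a Pearson r of 0.739 and a Spearman rho of 0.670; 236 genes rose in both where 24.6 would if the calls were independent, 356 fell in both where 38.2 would, and 1 went opposite ways. At day 13 r was 0.460 and rho 0.494, with 325 genes up in both against 51.4, 504 down in both against 96.6, and 4 opposite. In the 2 other divisions of the day 13 animals, with 1 control and 1 Eif3m animal on each side, r was 0.0409 and 0.0588. Among genes with a mean of at least 20 CPM r was 0.826 at day 9 and 0.735 at day 13. The 2 days share no animals: across 16444 genes their RNA changes had r of 0.239 and rho of 0.301, with 210 genes up on both days against 24.8, 302 down against 51.8 and 20 opposite, and across 12213 genes their footprint changes had r of 0.429 and rho of 0.423, with 336 up against 51.1, 417 down against 60.6 and 21 opposite. Genes are not independent replicates, so these coefficients carry no p.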

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

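The tests named in this part were chosen after the result was seen, except the tests of the difference between days, which were planned, and the sum over pseudogenes, which was written before its value was seen and replaced a first test that was void because too few genes had whole counts. Effects of Eif3m siRNA that differed between the days, by a test of the difference itself, drew attention in 202 genes in RNA, in 100 genes in footprints and in 33 genes in both. All of these 33 differed in the same direction in both assays, 29 lower and 4 higher at day 13. The 4 higher were C6, Ethe1, Gadd45a and Slc43a1, and the 29 lower include Col3a1, Col1a2, Lyz2, Lyve1, Csf1r, Vcam1 and Cd74, chosen after their values were seen. The stellate cell and fibrosis list, with a footprint median of -0.82 for day 13 minus day 9, differed in the same way. The list rose with Eif3m siRNA in day 9 footprints and fell in day 13 footprints, where its median is 0.07 under library totals and its call was lost with an estimated correlation (adjusted p = 0.09). The counts rest on single libraries of day 9 and day 13, as given above. Leaving out 1 day 9 library, 16 to 77 genes differed in RNA and 52 to 172 in footprints.

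Ribosomal protein genes were higher with Eif3m siRNA on both days. A scaling factor moves all genes alike. As in the list test, the list median lay above that of all genes by at least 0.46 (SE 0.02) over the 4 comparisons. Scaling alone would give no such gap, but this repeats the list test by which the pattern was found and adds no support. SEs in this part are over genes, not animals. Reads moved from pseudogenes would leave the sum unchanged, and the summed CPM of ribosomal protein, pseudogene and unnamed genes was higher by at least 0.25 in each comparison, with no overlap between groups. Pooled markers of other liver cell types had medians of 0.11 and -0.96 in RNA and 0.25 and -0.28 in footprints at day 9 and day 13, below ribosomal protein genes by at least 0.34 (SE 0.08), which argues against RNA from all those cells as the whole cause. In day 9 footprints stellate cell genes and neutrophil markers were at 0.50 and 0.65 against 0.78, so a part from these cells at day 9 stays open. A change in the livers that follows loss of Eif3m may explain the rise. This hypothesis was found on these data and was not tested, nor was a change in hepatocyte growth or feeding.

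The effect on the fibrosis list differed between the days. Footprints were made with 1 kit on both days and show the difference with a median of -0.82 (-0.89 to -0.75 leaving out each of 10 libraries in turn, highest adjusted p = 1.8e-16), which argues against the RNA kits as its cause. Fewer of all other cells at day 13 would lower endothelial genes alike, and their footprint median was -0.17 (SE of the difference 0.30). Lymphocyte and cholangiocyte lists, with 4 and 10 genes tested, had medians of 0.61 and 0.30 and did not pass. Macrophage, neutrophil and erythroid lists were at -0.80, -0.92 and -1.44 (erythroid -0.39 and -2.07 without day 13 control replicate 1 and 2, macrophage -0.52 without day 13 Eif3m replicate 2), and endothelial RNA was at -0.81, so fewer cells of several of these types stays open. Control livers were higher at day 13 than at day 9 by a median of 0.76 in footprints, and Eif3m livers differed by -0.08. A difference between the control mice of the 2 days and an effect of Eif3m siRNA over time cannot be told apart, since the days share no animals, and either may be the source.

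Many transcripts were nearly missing from day 13 RNA. Of 191 genes lost in control RNA (3.26% of 5852), 85.3% were lost in Eif3m RNA too. Their footprints changed by a median of 0.16 (SE 0.05) in controls, and 6 of them fell by over 1, which argues against loss of these messages from the livers. In the 2 day 13 Eif3m RNA libraries, which took no part in choosing these genes, 91.1% and 80.6% of them were lost, which argues against a single aberrant library. The preparation of the day 13 RNA may be the cause, and within it the kit and the run were not separable, and no biological explanation was tested beyond the footprints.

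The 6 day 9 animals divide 3 against 3 in 10 ways, too few for a share under 0.05. The real division gave 932 RNA genes and the highest other 0, so that 1 of the 10 gave as many. For footprints these were 1800 and 1, with 1 of the 10 as large. For efficiency edgeR called 0 genes in all 10. With an unadjusted p below 0.05 the real division had 692 genes and the others 114 to 258. The correlation of RNA and footprint changes was 0.739 in the real division and 0.474 in the highest other, where each other division sets 2 control and 1 Eif3m animal against 1 and 2 and so keeps part of the siRNA effect. The 4 day 13 animals divide 2 against 2 in 3 ways, also too few, with 0.460 in the real division and 0.0588 in the highest other.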

How the results depend on the processing

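The 4-fold alternative was chosen after seeing the data and the others were planned. Of 549 results for named genes, 245 kept their call under every alternative run; over 9329 values 7943 kept it, 1386 lost it and 0 reversed. Of 125 called lists 10 did. Over 1750 values 1522 kept the call, 228 lost it and 0 reversed, not counting medians that changed sign. RNA genes changed at day 9 numbered 1583 with no filter, 1626 with DESeq2 and 3445 with the day alone, and at day 13 968 with the day alone. RNA differences between days numbered 1034 with no filter, 728 with DESeq2 and 61 with the replicate block. Footprint genes numbered 2742 at day 9 and 2355 at day 13 with library totals, and differences between days 242 with no filter and 62 with the replicate block. Efficiency at day 9 gave 18 with no filter, 2 with DESeq2, 8 with the animal as a block and 4 with the day alone. At day 13 it gave 5 with DESeq2 size factors, 63 with library totals (56 up, 7 down), 145 with no filter, 6 with the stricter filter, 55 with DESeq2, 12 with the animal as a block, 93 with limma and 1 with the day alone, and between days 7, 2, 5 and 9 with no filter, DESeq2, the block and limma. With an estimated correlation the called lists fell from 17, 20 and 16 in RNA (day 9, day 13, difference) to 1, 5 and 0, from 18, 22 and 13 in footprints to 3, 0 and 1, and from 9, 6 and 4 in efficiency to 0, 0 and 0. With a mean of at least 20 CPM, RNA and footprint effects had r of 0.826 and 0.735 at day 9 and day 13, and the days 0.607 in RNA and 0.685 in footprints. Leaving out 1 library or animal at a time gave 292 to 2367, 1336 to 4266 and 0 to 2065 RNA genes, 1129 to 2179, 429 to 1875 and 7 to 172 footprint genes and 0 to 5, 0 to 438 and 0 to 59 efficiency genes. The lists ranged over 16 to 19, 18 to 21 and 14 to 17 in RNA, 16 to 20, 20 to 24 and 10 to 17 in footprints and 6 to 10, 3 to 6 and 1 to 5 in efficiency; efficiency at day 13 gave 3 lists without day 13 control replicate 2 or Eif3m replicate 1, and the difference 2 without day 13 control replicate 2 and 1 without Eif3m replicate 2. Genes within 4-fold between the days gave 629, 2025 and 150 of 13280 in RNA and 0, 4 and 0 of 11087 in efficiency, where fewer genes were tested. The cause was not tested for the rest. At day 13, with lower counts and 2 animals per group, 44% of simulated 4-fold efficiency changes were called, and depth was not separated from the number of animals.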

Other observations

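The tests of the vomeronasal genes and of the snoRNA host genes in this part were chosen after the result was seen, except the count of rises beside the vomeronasal genes. Replication-dependent histone genes, whose mRNAs lack a poly(A) tail and which share reads among close copies, rose with Eif3m siRNA in RNA at day 9 (3 of 9 called, 6 when adjusted over the list alone, median 0.81, adjusted p = 8.3e-05, and 0.12 with estimated correlation) and in footprints at day 9 (5 of 22, 8 when adjusted over the list alone, median 0.67, adjusted p = 2.0e-04, and 0.22 with estimated correlation) and day 13 (8 of 22, 12 when adjusted over the list alone, median 0.93, adjusted p = 2.3e-07, and 0.09 with estimated correlation). Immediate early genes passed in day 9 RNA (median 0.20, adjusted p = 0.039, and 0.59 with estimated correlation), lost with library totals (adjusted p = 0.077), with the replicate block (adjusted p = 0.12) and without day 9 control replicate 1 or 2 or Eif3m replicate 1 (adjusted p = 0.059, 0.29 and 0.06). They also passed in day 9 footprints (median 0.54, adjusted p = 0.015, and 0.39 with estimated correlation), lost without day 9 control replicate 2 or Eif3m replicate 1 (adjusted p = 0.095 and 0.088), and in day 13 footprints (median 0.52, adjusted p = 0.0048, and 0.29 with estimated correlation), lost without day 13 Eif3m replicate 2 (adjusted p = 0.057). The median was 0.12 in day 9 RNA without control replicate 2, 0.34 in day 9 footprints without control replicate 1, and 0.28 and 0.08 in day 13 footprints without control and Eif3m replicate 2. Proteasome genes passed in day 9 RNA with 0 of 31 called (median -0.17, adjusted p = 0.014, and 0.55 with estimated correlation), lost with library totals and without day 9 control replicate 3 (adjusted p = 0.12 and 0.072). Sex-biased liver genes passed in day 13 footprints (median -0.30, adjusted p = 0.005, and 0.09 with estimated correlation), with a median of 0.02 under library totals, lost without day 13 Eif3m replicate 2 (median -0.12, adjusted p = 0.094).

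Other lists did not pass in RNA or footprints at either day. Circadian clock genes had a median of -0.12 in RNA at day 9 (adjusted p = 0.81) and -0.19 at day 13 (adjusted p = 0.55), which became 0.01 at both days under library totals. Fetal and imprinted hepatocyte genes had 0.17 (adjusted p = 0.35) and -0.25 (adjusted p = 0.99), cholangiocyte markers -0.18 (adjusted p = 0.83) and -0.34 (test direction up, adjusted p = 0.98), and lymphocyte and natural killer markers 0.03 (test direction down, adjusted p = 0.95) and -0.86 (adjusted p = 0.53). Markers of kidney, pancreas and gut, tested with 5 genes in RNA, had 0.00 (adjusted p = 0.47) and -1.16 (test direction up, adjusted p = 0.79).

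In a run of 9 neighbouring genes, 8 vomeronasal (pheromone) receptor genes or pseudogenes were read in Eif3m livers and hardly in controls, and the predicted gene Gm34462, named after its values were seen, had 0 counts. Their summed counts (control, then Eif3m) were 0 and 122 in day 9 RNA and 9 and 3523 at day 13. In footprints they were 0 and 24, then 0 and 159. All 7 tested members rose in day 13 RNA, which the filter nearly forces at such low control counts. The 4 tested elsewhere had a median of 0.89 and 0 were called (edgeR), which argues against reads shared with these. Sharing within the run was not tested, and Vmn2r3 held 2551 of the 3523 counts. Of the 6 nearest genes outside the family 1 rose (Gmps at 0.60, named after its value was seen), which argues against a change of the whole chromosome stretch. Transcription from inside the run or read-through from a neighbour may explain it and was not tested.

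Gas5, Snhg1 and Snhg5, noncoding hosts of small nucleolar RNAs that guide rRNA modification, were higher in RNA with Eif3m siRNA on both days, a group chosen after its values were seen. Other host genes, with these 3 left out, had a footprint median of 1.96 at day 13 (4 of 8 called up, p = 5.5e-04, and p = 0.042 with an estimated correlation) and 0.81 at day 9 (4 of 8, p = 0.0087, and p = 0.057 with an estimated correlation). In RNA the median was 0.90 at day 13 (6 of 13, p = 1.9e-05, and p = 0.051 with an estimated correlation) and 0.12 at day 9 (4 of 13, p = 0.013, and p = 0.18 with an estimated correlation). A rise of this class is consistent with these values. Less decay of transcripts that are normally degraded when translated may explain it, and was not tested.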
